A study of Mus musculus with 2 samples.

How the data were processed

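The series measured RNA by sequencing in 2 libraries of type 5 retinal bipolar cells of the mouse, which form 1 group with replicates 1 and 2. Per the labels' protocols, retinas were dissociated, cells were sorted by fluorescence into RNAlater, and libraries of total RNA were made with the NuGEN Ovation RNA-seq system V2, an amplification kit for small RNA amounts. The design text calls the libraries biological replicates. Whether a library came from 1 animal or several, and the sex and age of the animals, is not given in the sources used here.

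The authors deposited 1 table of TPM (transcripts-per-million units), with a column per library. The submitters' processing notes name TopHat2 2.0.10, RSEM 1.2.28 and the genome build mm10, without saying which step each did. The annotation release, any filter, and whether strand was used in counting are not given in the sources used here. Reads of a gene and of an antisense gene that overlaps it may thus not be told apart, and reads shared by paralogs, pseudogenes or multi-copy RNAs can be split among them. The column of replicate 1 spells the gene of its name with letters exchanged and was matched by its replicate number to the library of that number. The columns sum to 999999.75 (replicate 1) and 999999.66 (replicate 2) over 32813 symbols, and this total includes ribosomal, mitochondrial and small RNAs, so a larger share of these lowers every other TPM. TPM keeps no depth. The depth per library is unknown, and no count test, counting interval or detection floor could be given.

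Values were taken as deposited and put on the scale log2(TPM + 1), with a pseudocount of 1. Genes at 0 in both libraries were left out of tests and no other filter was applied. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1. Expression above a line of 1 TPM, and of 10 TPM, was tested in limma with an intercept-only model and a variance trend, one-sided, with Benjamini-Hochberg adjustment over the 19968 genes and a threshold of 0.05. limma estimated an infinite prior for the variance (19968 total degrees of freedom for each gene), so each gene's variance was that of the trend at its abundance. Single adjusted p-values of genes are not printed because they inherit this assumption. In simulated data with 19968 genes, 0 of 50 genes set at 0.25 TPM, 10 of 50 at 4 TPM, 50 of 50 at 16 TPM and 50 of 50 at 64 TPM were called above 1 TPM, and 0 of 4407 genes simulated at or under 1 TPM were. Each simulated gene took the spread of genes of its abundance, as the fit assumes. The simulation therefore gives no error rate for real genes whose libraries differ far more than that.

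35 gene lists were fixed before the data were examined, from textbook knowledge of the retina, 18 of cell types and the others of functions and of sample quality. For each list the members above 1 TPM were counted over all genes and adjusted over the list alone. A list's level is the median over its members of the mean log2(TPM + 1), given with its percentile among 10000 random lists of the same size. These were drawn from genes above 0 in either library, so genes at 0 in both did not enter them. Differences between lists were tested by permuting list membership, two-sided, by exact enumeration where a list had fewer than 10 members and with 100000 resamples otherwise, and p-values were adjusted over the 15 differences. Genes are not independent replicates, so these tests describe lists within these libraries. A sign test over 2 libraries cannot go below p = 0.5 (exact, two-sided), so none was made between them. Differences between the libraries are given as medians over members above 0 with percentiles among 10000 random lists matched on expression in 20 bins, and as counts of genes with a mean of at least 10 TPM that differ by over 2 log2 units (4-fold). Mean ± SD of a gene's TPM is given over n = 2 libraries, except where a library lists 0. A difference between list medians is taken on values averaged over the libraries, so it is not the mean of the differences in each library, which are given beside it where it is printed on its own.

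Genes named in the text follow a rule fixed at the same time. It takes Htr3a and every member of the type 5, rod bipolar and other cone bipolar lists. Of every other list it takes up to 4 members with the highest and up to 2 with the lowest mean TPM, and any member of the ON bipolar, OFF bipolar, serotonin receptor, type II cadherin and bipolar transcription factor lists. It adds the 10 genes of highest mean TPM outside the mitochondrial genome and, per direction, the 5 genes of largest log2 difference between the libraries among those with a mean of at least 10 TPM. Members tied for a place count as taken, and some genes that the rule takes are not reported here. Gad1 and Gad2 are named beyond the rule and were chosen after their values were seen, as were genes of the closing section that are on none of the fixed lists. Coordinates, 1-based, and gene types come from GENCODE M21 on GRCm38, the same assembly as mm10, for the 30116 symbols that match 1 gene by name.

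Alternatives tried were a pseudocount of 0.1, quantile normalization, filters at 0.1 TPM in both libraries or a mean of 1 TPM, TPM rescaled without mitochondrial genes and the 10 most abundant other genes, limma without a variance trend, lines of 0.5 and 5 TPM, a mean of at least 50 TPM for differences, the mean over members in place of the median, both libraries over the line with no test, and each replicate left out in turn. Protein-coding nuclear genes alone, rescaled to the same total, were added after the data were seen.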

Results

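Bipolar cells carry visual signals from photoreceptors to the inner retina, and type 5 cells are a cone bipolar class whose axons end in the ON part of the inner plexiform layer. The series holds a single group, type 5 bipolar cells sorted by fluorescence from dissociated retina of the Htr3a-GFP mouse line, a line in which a green fluorescent protein marks cells with an active Htr3a promoter. It has 2 libraries of total RNA, described as biological replicates and called replicate 1 and replicate 2 here. Values are in transcripts-per-million units (TPM) for 32813 gene symbols. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. Of the symbols, 17975 were above 0 in replicate 1 and 18030 in replicate 2, and 12845 were at 0 in both. No other cell population belongs to the series, so each value below is a level in the sorted cells, not an enrichment over retina or over other bipolar types.

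The question that the design answers first is how closely the replicates match, since their spread sets the error of every other value. Genes at 100 to 1000 TPM were close in both libraries, and genes of low level were not. Across the 19968 genes above 0 in either library, log2(TPM + 1) of replicate 1 and replicate 2 correlated with Pearson's r of 0.864 and Spearman's rho of 0.836. This correlation is across genes, which are not independent replicates. The SD of a single library was 1.15 log2 units for the 6128 genes with a mean of 1 to 10 TPM, 0.842 for the 8216 genes at 10 to 100 TPM, 0.626 for the 1584 genes at 100 to 1000 TPM and 0.955 for the 64 genes at 1000 TPM or more. The genes at 1000 TPM or more include Xist, with a log2 difference of -8.63 (replicate 2 minus replicate 1), which raises their SD. An SD without Xist was not computed, so 0.955 does not show that the other abundant genes matched less closely. At 100 to 1000 TPM 90.8% of genes lay within 2-fold between the libraries, and at 1000 TPM or more 85.9%. The median gene was lower in replicate 2 by a log2 difference of -0.20. RNA from the mitochondrial genome took 17.3% of the TPM in replicate 1 and 24.6% in replicate 2, mostly ribosomal RNA at 13.2% and 19.8%.

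Zeros need care. Rps27, a ribosomal protein gene that every cell uses, was listed at 0 in replicate 1 and at 838 TPM in replicate 2. Of 79 ribosomal protein genes, 5 were listed at 0 in replicate 1 and 0 in replicate 2. A value of 0 is therefore given as listed, with each library's value.

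**Figure D1:**
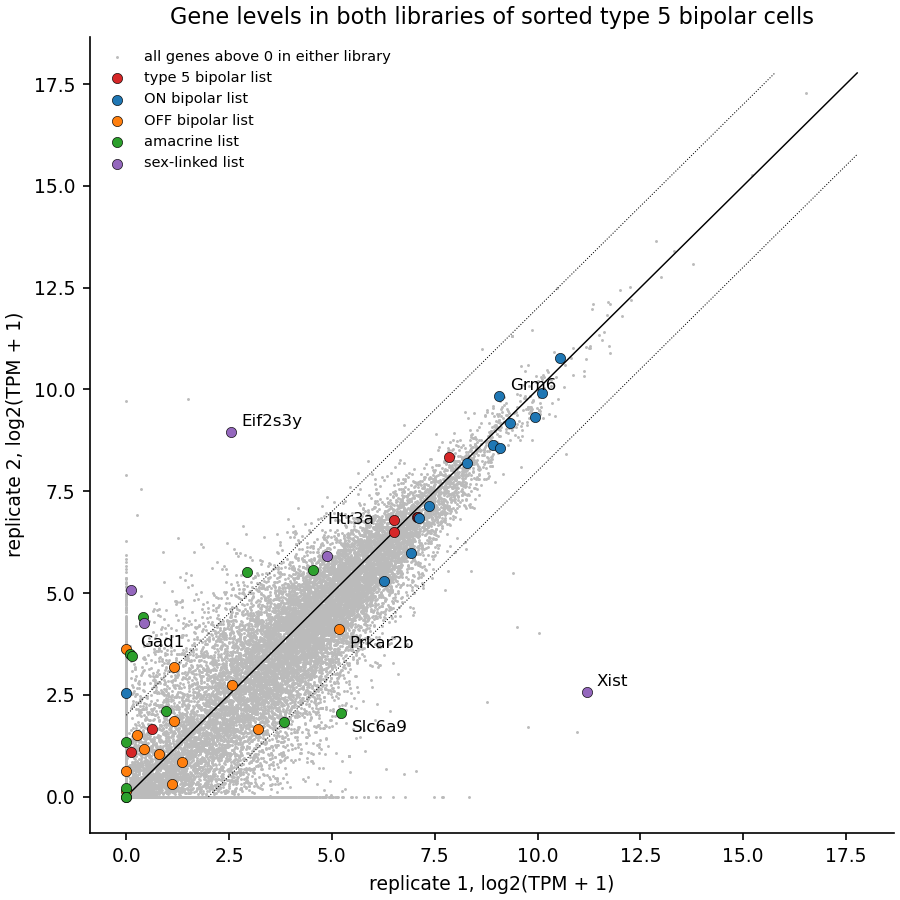
Each point is a gene, placed by its log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis). The solid line marks equal values and the dotted lines a log2 difference of 2. Grey points are the 19968 genes above 0 in either library and coloured points are members of 5 gene lists. Htr3a and Grm6 lie near the line of equal values, while Xist and Eif2s3y lie far from it on opposite sides.

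Expression above a line of 1 TPM was called for 11089 of the 19968 genes and above 10 TPM for 6475 (limma, one-sided, Benjamini-Hochberg adjusted p under 0.05). Of the 11089 genes, 11060 had at least 1 TPM in both libraries, 29 had less than 1 TPM in 1 library and 20 of these were listed at 0 in it. Protein-coding genes made up 9093 of the 11089. In this fit the variance of each gene came from the trend with abundance alone, so a gene's own disagreement between the libraries did not enter its call. Vim, an intermediate filament gene at 0.20 TPM in replicate 1 and 119 in replicate 2, was called on that basis. The counts without a test were 15514 genes at or over 1 TPM in replicate 1 and 14882 in replicate 2, and 9935 and 9294 at or over 10 TPM. A gene not called was not shown to lie under 1 TPM, because in simulated data 20% of genes set at 4 TPM and 100% of genes set at 16 TPM were called.

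The sorted cells expressed the marker used for the sort and most of the genes that mark type 5 cells. Htr3a, the ion channel subunit of the serotonin receptor 3A, stood at 89.9 ± 1.48 TPM (SD, n = 2) and ranked 1893 among all symbols by mean TPM. Kcng4, a modifier subunit of voltage-gated potassium channels, stood at 277 ± 68.7 TPM, and Cdh9, a type II cadherin, at 125 ± 11.8 TPM. Of the genes that part the type 5 subtypes, Sox6, a transcription factor gene of subtype 5A, stood at 126 ± 15.2 TPM and Lrrtm1, a synaptic adhesion gene of subtype 5D, at 100.2 ± 13.7 TPM (SD, n = 2). Chrm2, a muscarinic receptor gene of subtype 5B, had 0.08 TPM in replicate 1 and 1.15 in replicate 2. Slitrk5, a transmembrane adhesion gene of subtype 5C, had 0.55 and 2.15 TPM. Of the 7 genes on the type 5 list, 5 were above 1 TPM over all genes tested and 5 adjusted over the list alone, and the same number was above 10 TPM. Htr3a, on whose promoter the cells were sorted, is among the 5.

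The type 5 genes are protein-coding in GENCODE M21 on GRCm38, the assembly also called mm10. Htr3a lies on chromosome 9 from 48899213 to 48911099 on the minus strand and Kcng4 on chromosome 8 from 119623854 to 119635680 on the minus strand. Cdh9 lies on chromosome 15 from 16728756 to 16857094 on the plus strand and Sox6 on chromosome 7 from 115470872 to 116038796 on the minus strand. Chromosome 6 carries Lrrtm1 from 77242689 to 77257791 and Chrm2 from 36388084 to 36528414, both on the plus strand. Slitrk5 lies on chromosome 14 from 111675097 to 111683141 on the plus strand. TPM values are per gene, so they do not say which exons or transcripts were read.

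Of 5 rod bipolar genes, Rpa1, which encodes a subunit of replication protein A, stood at 40.0 ± 9.50 TPM and was the 1 member above the 1 TPM line. Prkca, the protein kinase C gene by which rod bipolar cells are usually stained, stood at 5.70 ± 2.26 TPM, Vstm2b at 4.06 ± 2.68, and Car8 at 3.75 ± 1.02 TPM (SD, n = 2). Of 10 genes of other cone bipolar types, 3 were above the line: Nnat at 32.1 ± 16.9 TPM, Lect1 at 28.7 ± 20.1 and Serpini1 at 17.3 ± 4.91. Cpne9 stood at 5.21 ± 3.30 TPM, Pcdh10 at 4.65 ± 1.56, Pcdh17 at 1.80 ± 2.29 and Col11a1 at 1.24 ± 1.41. Igfn1 stood at 0.34 ± 0.08 TPM. Cck and Irx6 were listed at 0 in replicate 1 and at 3.06 and 0.08 TPM in replicate 2. The other limma settings gave counts of 1 to 4 rod bipolar and 3 to 5 other cone bipolar genes. Without a test, 5 of the 5 rod bipolar genes had at least 1 TPM in replicate 1, 4 in replicate 2 and 4 in both, and of the 10 other cone bipolar genes 6, 7 and 5.

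The median of the type 5 list was 6.65 on the log2(TPM + 1) scale, against 2.23 for the rod bipolar list and 1.83 for the other cone bipolar list. The type 5 median exceeded that of the other cone bipolar list by 4.82 on values averaged over the libraries (exact permutation test over list membership, two-sided p = 0.0283, adjusted p = 0.0304). It was higher in both libraries, by 4.30 in replicate 1 and 4.71 in replicate 2, and the test without replicate 2 did not pass (adjusted p = 0.105, exact permutation test). The difference from the rod bipolar list, 4.42 on averaged values, 4.512 in replicate 1 and 3.997 in replicate 2, did not pass (exact permutation test, p = 0.179, adjusted p = 0.179), with only 5 genes on that list. These tests permute genes, which are not independent replicates, and their p-values were adjusted over a family of 15 differences between lists. A difference on the log2(TPM + 1) scale understates the fold between genes of low level. The type 5 list includes Htr3a, on whose promoter the cells were sorted, so that member is no independent sign of type 5 cells. The differences were not tested without Htr3a.

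**Figure D2:**
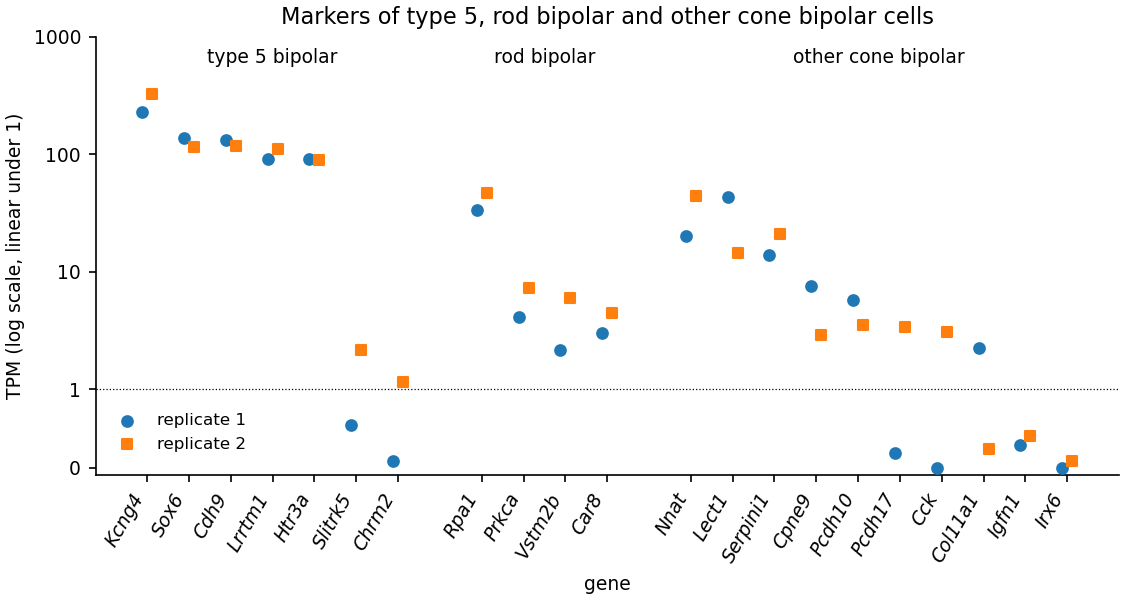
TPM (y axis, log scale that is linear under 1) of 21 genes on the type 5, rod bipolar and other cone bipolar lists, in replicate 1 (circles) and replicate 2 (squares), with genes ordered by mean TPM and a dotted line at 1 TPM. The 5 highest type 5 genes lie between 88.8 and 326 TPM in both libraries, and the highest gene of the other lists, Rpa1, at 33.3 and 46.7 TPM.

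Of 13 genes of ON bipolar cells, which depolarise when light increases, 12 were above 1 TPM and 12 above 10 TPM. Grm6, the glutamate receptor at the head of the ON cascade, stood at 726 ± 265 TPM and Trpm1, its cation channel, at 812 ± 249 TPM (SD, n = 2). Their G protein subunit genes were similarly abundant, with Gnao1 at 1624 ± 184 TPM, Gng13 at 1026 ± 100 and Gnb3 at 609 ± 47.2. Gpr179 stood at 303 ± 12.8 TPM, Nyx, which encodes nyctalopin, at 151 ± 16.3, and the regulators of G protein signalling Rgs11 and Rgs7 at 125 ± 16.8 and 57.4 ± 26.9. Isl1, the ON bipolar homeobox gene, stood at 461 ± 117 TPM and Pcp2 at 441 ± 63.98. Lrit3 was the 1 of 13 ON genes not above 1 TPM, listed at 0 in replicate 1 and at 4.87 TPM in replicate 2.

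Of 13 OFF genes, Prkar2b, a regulatory subunit of protein kinase A, was the 1 above the line, at 25.6 ± 13.3 TPM. Grik1, the kainate receptor subunit of OFF bipolar cells, stood at 1.94 ± 1.0 TPM, Vsx1 at 0.90 ± 0.23, Tacr3 at 0.71 ± 0.66 and Hcn4 at 0.80 ± 0.64 (SD, n = 2). Cdh8 stood at 5.34 ± 0.50 TPM, Csn3 at 5.18 ± 4.25, Bhlhe22 at 4.70 ± 4.88, Fezf2 at 1.17 ± 0.54 and Erbb4 at 1.03 ± 1.19. Neto1, Syt2 and Lhx3 were listed at 0 in replicate 1, and had 11.2, 0.54 and 0.11 TPM in replicate 2. Without a test, 7 OFF genes were at or over 1 TPM in replicate 1, 9 in replicate 2 and 5 in both. The ON median of 8.78 exceeded the OFF median of 1.10 by 7.68 log2 units on values averaged over the libraries (permutation test, two-sided, adjusted p = 0.0024). The difference was 7.80 in replicate 1 and 7.05 in replicate 2. The ON list holds genes of the shared ON cascade, whereas some OFF genes mark single OFF types. The gap is thus no measure of ON against OFF cells. Random lists of the same size, 10000 in number, were drawn from genes above 0 in either library. Among them the ON median lay at percentile 100 and the OFF median at percentile 1.63. Adjusted over the list alone, the counts were also 12 of 13 and 1 of 13.

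The median of the pan-bipolar list stood above the list median of every other retinal class examined, though single members overlapped. Of 14 pan-bipolar genes, 13 were above 1 TPM over all genes and 13 adjusted over the list alone. Cabp5, a calcium-binding protein, stood at 1336.5 ± 385 TPM, Neurod4 at 1178 ± 130 TPM, Trnp1 at 1098 ± 58.5, and Otx2, a homeobox gene shared by photoreceptors and bipolar cells, at 859 ± 22.6 TPM (SD, n = 2). The lowest members were Six3 at 18.1 ± 7.57 TPM and Unc13c at 0.94 ± 0.76, the latter not above the line. The list median was 8.23.

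Rod photoreceptor genes were the main class of other markers, with 12 of 15 above 1 TPM and 9 above 10 TPM. Gngt1, a transducin subunit, stood at 802 ± 230 TPM, Rom1 at 327 ± 33.5 and Sag, the rod arrestin, at 248 ± 0.64 TPM (SD, n = 2). The lowest were Cnga1 at 4.20 ± 3.29 and Nr2e3 at 2.76 ± 2.61. Of 10 cone photoreceptor genes, 3 were above 1 TPM: Gnat2 at 54.6 ± 44.4 TPM, Gngt2 at 47.7 ± 50 and Thrb at 13.1 ± 3.67. Pde6h followed at 5.54 ± 3.49, Cnga3 had 1.77 ± 0.14, and Pde6c had 0.46 TPM in replicate 1 and was listed at 0 in replicate 2. The other limma settings gave 3 to 5 cone genes, and without a test 9 were at or over 1 TPM in replicate 1, 8 in replicate 2 and 8 in both.

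Muller glia had 6 of 11 genes above the line, among them Glul, the glutamine synthetase gene, at 99.8 ± 34.1 TPM, Clu at 82.6 ± 4.44 and Dkk3 at 21.4 ± 14.4. Amacrine cells had 4 of 12 above the line over all genes and 3 adjusted over the list alone. Pax6 stood at 34.4 ± 17.1 TPM, Slc6a9, a glycine transporter, at 19.8 ± 23.6 and Tfap2b, which was not above the line, at 10.4 ± 14.2, while Chat and Calb2 were listed at 0 in both libraries. Without a test, 8 Muller glia genes were at or over 1 TPM in replicate 1, 10 in replicate 2 and 7 in both, and of the amacrine genes 4, 9 and 4. Of 10 ganglion cell genes only Thy1 was above the line, at 46.1 ± 25.1 TPM, with Rbpms at 6.08 ± 4.0, and Nefm and Sncg listed at 0 in both libraries, while 2 ganglion cell genes were at or over 1 TPM in replicate 1, 3 in replicate 2 and 2 in both without a test. No member of the horizontal, microglia, endothelial, pericyte, astrocyte or pigment epithelium lists, 33 genes in all, was above 1 TPM by limma over all genes or adjusted over the list alone, and 1 of the 33, the pigment gene Tyr at 5.84 ± 1.55 TPM, was above it at an unadjusted p under 0.05. Other limma settings called at most 1 pigment epithelium gene and 1 microglia gene, and without a test 2 microglia genes, 1 endothelial gene and 1 pigment epithelium gene were at or over 1 TPM in both libraries. The highest microglia entry, Aif1, was listed at 0 in replicate 1 and at 13.0 TPM in replicate 2, the highest horizontal cell gene, Calb1, had 0.51 and 9.28 TPM, and Gfap of astrocytes was listed at 0 and at 3.40 TPM. Pecam1 of endothelial cells had 1.5 ± 0.42 TPM and Rgs5 of pericytes 0.56 ± 0.63. Of 5 red blood cell genes 3 were above the line, with Alas2 at 33.6 ± 3.75, Hba-a1 at 12.1 ± 2.27 and Hbb-bs at 10.1 ± 2.37 TPM (SD, n = 2).

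The pan-bipolar median exceeded the rod median by 2.85 log2 units on values averaged over the libraries (permutation test, adjusted p = 0.0304), the smallest gap of the 12 classes. The gap was 4.17 in replicate 1 and 2.60 in replicate 2. Pan-bipolar genes exceeded red blood cell genes by 4.77 (4.36 in replicate 1 and 4.98 in replicate 2; exact permutation test, adjusted p = 0.0197), Muller glia genes by 5.23 (6.52 and 4.61) and cone genes by 6.25 (5.80 and 6.45; permutation test, adjusted p = 0.00277 for each). For amacrine cells the gap was 6.43 (7.96 and 6.14) and for ganglion cells 8.17 (8.17 in both; permutation test, adjusted p = 0.0024 for each). The gaps to the horizontal, microglia, endothelial, pericyte, astrocyte and pigment epithelium lists lay between 7.43 and 8.23, with adjusted p from exact permutation tests between 0.00271 and 0.014. All 12 gaps had the same direction in both libraries.

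**Figure D3:**
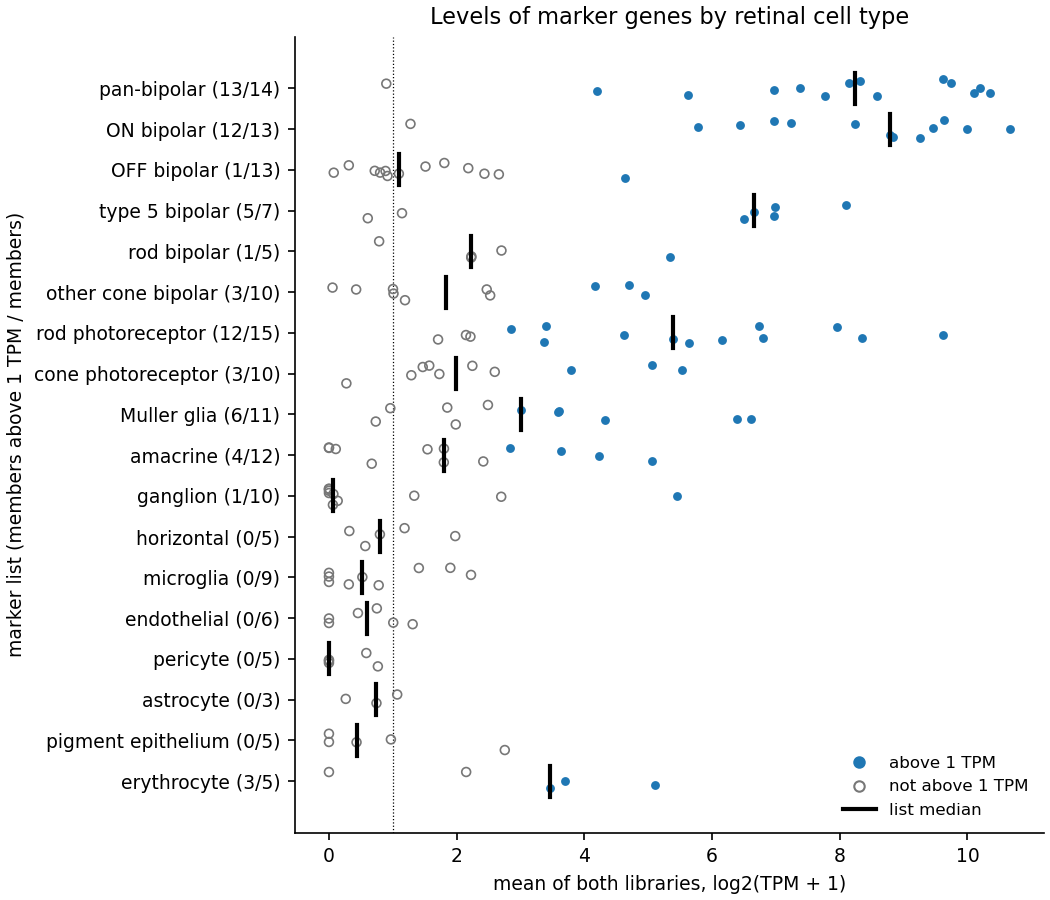
Mean log2(TPM + 1) of both libraries (x axis) for each member of the 18 cell type lists (rows), with the list median as a vertical bar, filled points for genes above 1 TPM, open points for the others, and a dotted line at 1 TPM. The medians of the pan-bipolar, ON and type 5 lists lie at 8.23, 8.78 and 6.65, and that of the rod list at 5.38, above every remaining list.

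Genes of the ribbon synapse, the release site of bipolar cells and photoreceptors, were expressed almost without exception, with 16 of 17 above 1 TPM over all genes and adjusted over the list alone. Snap25 stood at 2012 ± 425 TPM, Cplx4, a complexin of ribbon synapses, at 943 ± 180, Vamp2 at 453 ± 12.7 and Syt1 at 437 ± 78.6 (SD, n = 2). The lowest were Erc2 at 17.1 ± 11.6 and Cabp4 at 0.55 ± 0.55, the latter not above the line.

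Of 18 ionotropic glutamate receptor subunits 7 were above 1 TPM over all genes and 6 adjusted over the list alone, led by the AMPA subunit Gria2 at 169 ± 8.08 TPM, the NMDA subunit Grin1 at 111 ± 1.31, Gria1 at 43.3 ± 12.6 and the kainate subunit Grik5 at 24.4 ± 0.18 (SD, n = 2). Grin2a and Grin2c, which encode partners of Grin1 in NMDA receptors, were listed at 0 in both libraries. Of 8 metabotropic receptors, Grm6 and Grm5 were the 2 above the line, with Grm5 at 58.3 ± 28.3 TPM. Grm7 had 2.37 ± 1.15 TPM, while Grm2 and Grm3 were listed at 0 in replicate 1 and at 1.90 and 0.03 TPM in replicate 2. The metabotropic count was also 2 of 8 adjusted over the list alone. Without a test, 11 ionotropic genes were at or over 1 TPM in replicate 1, 12 in replicate 2 and 10 in both, and of the metabotropic genes 3, 5 and 3.

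Of 21 GABA receptor subunits 11 were above 1 TPM, and 7 above 10 TPM. Among them were Gabrr2 at 787 ± 73.9 TPM and Gabrr1 at 384 ± 46.7, with the metabotropic subunit Gabbr2 at 163 ± 30.1 (SD, n = 2). Gabrp and Gabrq were listed at 0 in both libraries. Of 5 glycine receptor subunits 2 were above the line, Glrb at 16.7 ± 2.02 and Glra3 at 7.83 ± 3.83, with Glra1 at 3.50 ± 2.44, Glra4 at 1.0 ± 1.05 and Glra2 at 0.36 ± 0.30.

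Among 14 serotonin receptors, Htr3a was the 1 gene above the line. Htr3b, whose product joins Htr3a in a mixed channel, had 3.94 ± 1.94 TPM, Htr1b 0.84 ± 0.71 and Htr7 0.44 ± 0.42 (SD, n = 2). Htr2b had 9.17 TPM in replicate 1 and 0.45 in replicate 2, and Htr1a, Htr1d and Htr4 were listed at 0 in both. Of 18 acetylcholine receptors, 4 nicotinic subunits were above 1 TPM and 0 members above 10 TPM, by limma with or without adjustment of p. Chrna7 stood at 18.4 ± 13.8 TPM, Chrnb2 at 14.95 ± 0.47, Chrnb1 at 14.5 ± 5.11 and Chrna4 at 12.3 ± 3.61, while Chrna6 and Chrna9 were listed at 0 in both libraries. Each of the GABA, glycine, serotonin and acetylcholine counts above 1 TPM was the same adjusted over the list alone. Without a test, 9 acetylcholine receptor genes were at or over 1 TPM in replicate 1, 9 in replicate 2 and 8 in both, of the serotonin receptors 4, 2 and 2, and of the glycine receptors 4, 3 and 3.

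Voltage-gated channel genes were expressed in each family. Calcium channel alpha1 genes were above 1 TPM in 8 of 10, led by the T-type gene Cacna1h at 320.1 ± 79.8 TPM, the L-type gene Cacna1f of ribbon synapses at 190.5 ± 79.8, Cacna1g at 66.2 ± 6.81 and Cacna1b at 31.0 ± 6.07 (SD, n = 2). The lowest were Cacna1i at 3.73 ± 1.36 and Cacna1c at 1.12 ± 1.25. Sodium channel genes were above the line in 4 of 13, with Scn8a at 34.6 ± 10.6 TPM, Scn2a1 at 25.1 ± 6.77, Scn3a at 20.6 ± 1.68 and the beta subunit Scn2b at 7.67 ± 1.30, while Scn11a and Scn4b were listed at 0 in both libraries. Without a test, 7 sodium channel genes were at or over 1 TPM in replicate 1, 7 in replicate 2 and 6 in both. Of 4 genes for channels opened by hyperpolarisation, 2 were above the line, among them Hcn3 at 12.6 ± 7.94 TPM, and Hcn4 at 0.80 ± 0.64 was not. Of 8 connexins Gjd2, which encodes connexin 36 of neuronal gap junctions, was the 1 above the line, at 149 ± 18.4 TPM. Gjc1 had 7.45 and 0.87 TPM, Gja5 was listed at 0 in replicate 1 and at 0.27 TPM in replicate 2, and the connexins Gja1 and Gja10 were listed at 0 in both. These counts were the same adjusted over the list alone. Without a test, 2 connexins were at or over 1 TPM in replicate 1 and 1 in replicate 2.

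Type II cadherins, adhesion proteins by which bipolar types can be told apart, had 5 of 13 genes above 1 TPM. Cdh11 was the highest at 296 ± 0.74 TPM, above Cdh9 at 125 ± 11.8, Cdh20 at 48.8 ± 14.2, Cdh10 at 26.01 ± 3.01 and Cdh18 at 11.0 ± 1.77 (SD, n = 2). Cdh8 stood at 5.34 ± 0.50 and was not above the line. Without a test, 7 type II cadherins were at or over 1 TPM in replicate 1, 9 in replicate 2 and 7 in both. Of 33 transcription factors, 16 were above 1 TPM and 13 above 10 TPM. Neurod4, Otx2, Isl1, Lhx4 and Sox6 were among them, and so were St18 at 758 ± 189 TPM, Nfia at 561 ± 28.3, Crx at 260.5 ± 17.4, Nfix at 178 ± 25.2, Neurod1 at 121 ± 3.67 and Six6 at 36.1 ± 1.78. None of the 6 Irx genes was above the line, of which Irx3 was the highest at 5.84 ± 0.91 TPM and Irx1, Irx2, Irx4 and Irx5 were listed at 0 in both libraries. By limma, Irx3 was the 1 Irx gene above 1 TPM at an unadjusted p under 0.05. Both list counts above 1 TPM were the same adjusted over the list alone.

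**Figure D4:**
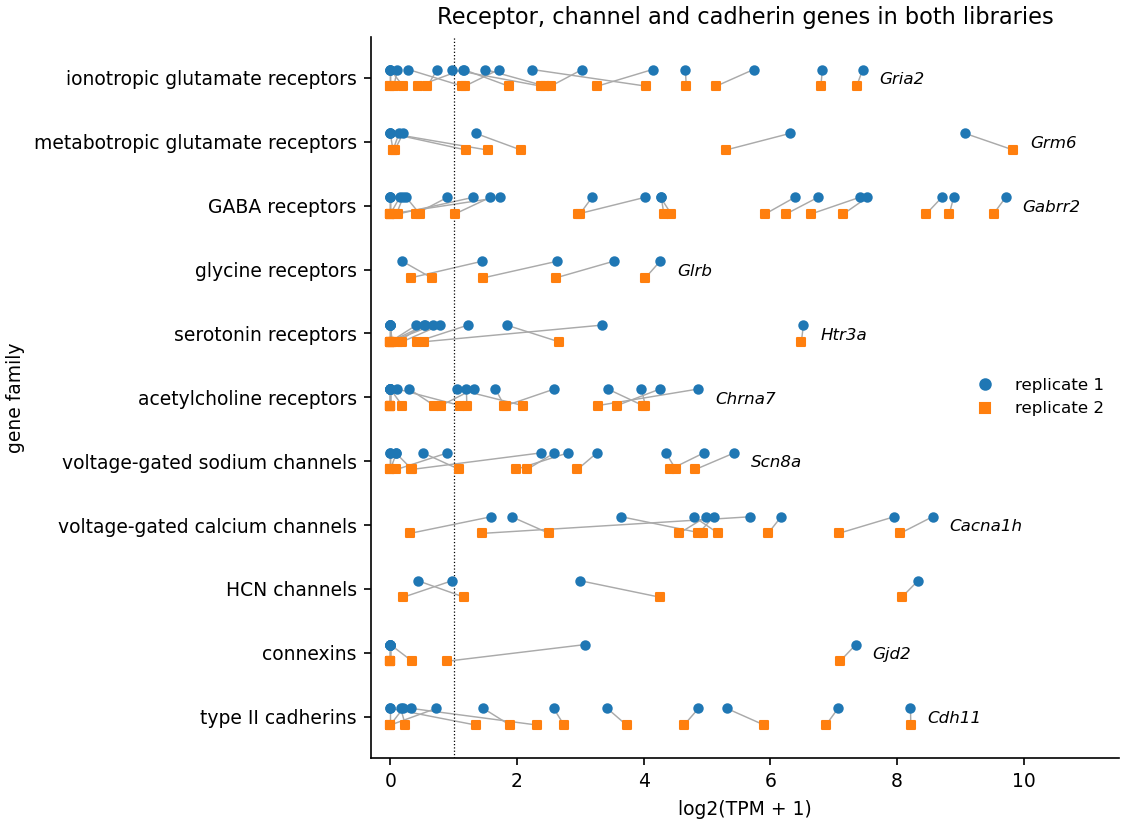
Log2(TPM + 1) (x axis) of every gene in 11 receptor, channel and cadherin families (rows), in replicate 1 (circles) and replicate 2 (squares), with a line joining the values of a gene, the member of highest mean TPM named in 10 of them, and a dotted line at 1 TPM. Htr3a stands alone among the serotonin receptors, at 90.9 and 88.8 TPM.

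Outside the mitochondrial genome, the most abundant symbols were the nuclear noncoding RNA Malat1 at 11413 ± 3828 TPM and Gm26924 at 10149 ± 3759 TPM. A separate entry of the same RNA family, MALAT1, stood at 3950.1 ± 831 TPM, and reads of the Malat1 locus could fall to either entry. Also among the 10 highest were Gapdh, a glycolysis gene, at 7585 ± 879 TPM, Mgarp, a mitochondrial protein gene, at 3911 ± 514, Atp5b, an ATP synthase subunit, at 3463 ± 242 and Pfkp, a phosphofructokinase, at 2919 ± 302 (SD, n = 2). The microRNA-type entry Gm25732 at 3565 ± 3043 TPM, Hnrnph1 at 2763 ± 897 and Gm4792 at 2712 ± 456 complete the 10 highest.

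Housekeeping genes were above 1 TPM in 16 of 16 and protein genes of the mitochondrial genome in 13 of 13, over all genes and adjusted over the list alone. Ywhaz stood at 1029.9 ± 11.2 TPM, Eef1a1 at 905 ± 14.8 and B2m at 11.6 ± 14.9, and mt-Co1 at 10467 ± 428 TPM (SD, n = 2). Genes induced by cell dissociation were above the line in 8 of 18, over all genes and adjusted over the list alone, and without a test 12 were at or over 1 TPM in replicate 1, 13 in replicate 2 and 9 in both. The constitutive chaperone gene Hspa8 stood at 987 ± 145 TPM, Hsph1 at 155 ± 15.5, Dnajb1 at 116 ± 13.6 and the immediate early gene Egr1 at 185 ± 168, with 304 TPM in replicate 1 and 66.3 in replicate 2. Atf3 had 0.28 ± 0.24 TPM, and Hspa1b was listed at 0 in replicate 1 and at 0.70 TPM in replicate 2.

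The libraries differed in sex-linked genes and in some markers of other retinal cells, while the bipolar lists differed little. Xist, the noncoding RNA of X inactivation, had 2339 TPM in replicate 1 and 4.90 in replicate 2. The Y-linked genes went the other way, with Eif2s3y at 4.88 and 494 TPM, Kdm5d at 0.08 and 32.5, and Ddx3y at 0.35 and 18.1, while Uty had 28.4 and 59.3 TPM. By limma, 3 of the 5 sex-linked genes were above 1 TPM, over all genes and adjusted over the list alone, and without a test 3 were at or over it in replicate 1 and 5 in replicate 2. The median difference of replicate 2 minus replicate 1 was 0.12 log2 units for the pan-bipolar list, -0.22 for the ON list and 0.28 for the type 5 list, all within the central 95% of random lists matched on expression.

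Rod genes were higher in replicate 2 by a median of 1.09, with 12 of 15 members higher, at percentile 100 of 10000 matched random lists. The most abundant members shared little of this rise. Gngt1 was lower in replicate 2 (965 and 639 TPM), Sag was level (248 in both) and Rom1 was slightly higher (303 and 351). Amacrine genes were higher by 1.24 (percentile 99.8, 8 of the 10 members above 0), Muller glia genes by 0.69 (percentile 98.8, 9 of 11) and ganglion cell genes by 0.48 (percentile 99.3, 4 of the 6 members above 0). The ganglion cell difference rests mostly on low values, since Thy1 was the only member above 1 TPM. Cone genes lay the other way, at -0.84 (percentile 6.19). Among amacrine genes Gad1 and Gad2, which encode enzymes of GABA synthesis and were chosen after their values were seen, had 0.06 and 0.11 TPM in replicate 1 and 10.4 and 9.94 in replicate 2, whereas Slc6a9 had 36.5 and 3.12. Genes of the mitochondrial genome were higher in replicate 2 by 0.27 (percentile 99.2), metabotropic glutamate receptors by 0.38 (percentile 99.03) and sex-linked genes by 3.82 (percentile 100). Each is a difference between 2 libraries with no replicate check, and chance places about 5% of the 35 lists outside the central 95%.

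Among the 9864 genes with a mean of at least 10 TPM, 240 were over 4-fold higher in replicate 2 and 396 over 4-fold higher in replicate 1. Which direction held more genes depended on the setting, with 336 in replicate 2 and 291 in replicate 1 after quantile normalization. The counts were 265 and 262 with protein-coding genes only and 411 and 432 when rescaled without mitochondrial and the 10 most abundant other genes. These last settings changed both the genes kept and the scaling. After Xist and the entries for its exons, the largest differences toward replicate 1 were those of Gm10800, at 875 and 2.29 TPM, and Gm26635, at 207 TPM and listed at 0 in replicate 2. Toward replicate 2 they were those of Rps27, then Gm20594 at 1.82 and 864 TPM, Gm22758, listed at 0 in replicate 1 and at 239 TPM, Rps3a3, a processed pseudogene, at 0.28 and 186 TPM, and Vim. Pseudogenes and multi-copy entries share reads with their copies, so their own levels are uncertain.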

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

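The setting with protein-coding genes only was chosen after the data were seen, and the others before. Of 117 alternative values of the 15 differences between lists, 116 kept their direction and side of the threshold and 0 reversed. The exception was type 5 minus other cone bipolar, 4.30 to 4.71 over the libraries left out, which no longer passed without replicate 2 (adjusted p = 0.105), where a single library remains. Of the 62 genes on the bipolar lists, 35 were above 1 TPM and 0 of these lost the call under the other limma settings at that line, while 8 others gained it under at least 1. The number above 1 TPM moved by less than 1.5 times throughout, and the number above 10 TPM was 9294 to 9935 with a library left out, a count with no test. The OFF count of 1 was 3 with pseudocount 0.1, 4 with the 0.1 TPM filter, 2 rescaled, 4 with protein-coding genes only, 3 without the variance trend, 5 with both libraries over the line, and 7 to 9 with a library left out. OFF genes lie near the 1 TPM line, where the self-test called 20% of genes set at 4 TPM.

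Pearson's r between the libraries was 0.773 with pseudocount 0.1, 0.795 at a mean of at least 1 TPM, 0.853 rescaled and 0.896 with protein-coding genes only. Genes over 4-fold higher in replicate 2 and in replicate 1 numbered 240 and 396, and the excess toward replicate 1 depended on the setting. It turned with quantile normalization (336 and 291), nearly vanished rescaled (411 and 432) and turned by a small margin with protein-coding genes only (265 and 262). The rescaled and protein-coding settings changed the genes kept as well as the scaling, so their counts do not single out scaling. The numbers were 276 and 441 with pseudocount 0.1, and 33 and 36 at a mean of at least 50 TPM. List medians on the log2(TPM + 1) scale rose when rescaled, to 8.67 (pan-bipolar), 9.22 (ON) and 7.09 (type 5), and with protein-coding genes only, to 8.89, 9.43, 7.30 and, for OFF, 1.47, because the remaining genes share the whole TPM total. As means over members they were 7.71 (pan-bipolar), 7.89 (ON), 5.28 (type 5) and 1.54 (OFF). At a mean of at least 1 TPM, which removes low members, the pan-bipolar median was 8.31 and the OFF median 1.99. With pseudocount 0.1 the OFF median was 0.091, and it was 1.12 to 1.52 with a library left out. The difference of Muller glia genes between the libraries was 1.42 as a mean over members, and that of amacrine genes 2.22 with pseudocount 0.1 and 1.87 at a mean of at least 1 TPM. Causes were not tested where none is named. With the depth unknown, low values such as the 0.08 TPM of Chrm2 in replicate 1 cannot be given an error from counting.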

Other observations

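The gene lists of this paragraph and the next were chosen after their values were seen, and so were the tests further on, except those on rod, Muller glia and amacrine genes outside the fixed lists, which were written before those values were seen, while the comparison of a gap with the spread of the members was added after. Of 19 glycolysis genes 18 were above 1 TPM and 17 above 10 TPM. Pfkp was the main phosphofructokinase at 2919 ± 302 TPM, against Pfkm at 65.5 ± 14.7 and Pfkl at 59.6 ± 8.91, and Pgam1 stood at 2302 ± 229 and Aldoa at 1772 ± 23.8 TPM (SD, n = 2). Lactate dehydrogenase was mostly Ldha, at 857 ± 43.1 TPM against 36.9 ± 3.61 for Ldhb. Of the dopamine receptors, Drd1a stood at 259.6 ± 30.8 TPM and Drd2, of the opposite signalling class, at 174 ± 3.14, while Drd3 and Drd5 were listed at 0 in both libraries and Drd4 at 0 in replicate 1 and 8.72 TPM in replicate 2. Of 18 neuropeptide and histamine receptors 3 were above 1 TPM: Vipr2, a receptor of vasoactive intestinal peptide, at 504.5 ± 56.3 TPM, Hrh3, a histamine receptor, at 37.3 ± 21.6 and Adcyap1r1 at 10.8 ± 8.30.

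Slc12a5, the chloride extruder KCC2, stood at 688 ± 6.24 TPM and Slc12a2, a chloride importer, at 22.7 ± 1.12. The glutamate transporter gene Slc1a2 stood at 795 ± 225 TPM and Slc1a7 at 7.66 ± 2.21 (SD, n = 2). Of 26 potassium channel genes 19 were above 1 TPM. Kcng4, whose product is silent without a partner, stood at 277 ± 68.7 TPM beside Kcnb2, a partner gene of its class, at 193 ± 24.7. Kcnh6 stood at 216 ± 32.5 TPM, the calcium-activated Kcnma1 at 212 ± 7.66 and Kcnj14 at 125 ± 0.49. Of 33 adhesion and guidance genes 21 were above 1 TPM, led by Nrxn3 at 813 ± 178 TPM, Epha7 at 585 ± 108, Cntn4 at 160 ± 54.7 and Robo2 at 151 ± 59.3. Dscam, Sdk1, Sdk2 and Robo1 were not above the line, with 3.64 ± 3.57, 0.91 ± 0.44, 1.83 ± 1.29 and 0.10 ± 0.01 TPM.

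Markers of rods, Muller glia and amacrine cells were higher in replicate 2, and with 1 group no biological explanation was tested. The rod list exceeded the cone list by 1.93 log2 units, against a matched limit of 0.99 and a spread of the members of 1.52. The test took a lower share of bipolar cells in replicate 2 to raise markers of all other classes alike. The gap argues against such an even rise only. A sort that let in rods without cones would break that premise, so the test does not decide on the share of bipolar cells. Genes outside the list, chosen as rod genes, had a median difference of 0.17 (percentile 90.5). This was below the 1.09 of the list by more than the limit from matched medians (SD 0.327) that was written before. But that limit left out the spread of the members (SD 1.92). Of the 16 members, 5 were over 4-fold higher in replicate 2, such as Rcvrn at 1.30 and 16.1 TPM, and 1 over 4-fold higher in replicate 1. Some of these genes, Rcvrn among them, are not specific to rods, so the check cannot single out rods. More rod RNA therefore stays open. Further Muller glia genes had a median of 1.19 (percentile 99.9, 11 of 12 higher). Only 2 of the 14 genes chosen for this were above 1 TPM, and most had low values. Sparc was higher in replicate 2 (19.1 and 58.6 TPM) but Cd9 lower (30.1 and 16.3). Further amacrine genes had a median of 0.54 (percentile 97.7, 6 of 11 higher, Elavl3 at 0.08 and 6.58 TPM but Meis2 at 408 and 335). RNA of these cells in the sort of replicate 2 may therefore account for their part, although a fluorescence sort is meant to remove such cells. The low values leave such a source uncertain for both classes, and the split of the amacrine genes does so further. Matched random lists draw each gene on its own, so noise shared by the genes of a list stays open as well.

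Xist and the Y-linked genes split the libraries. With animals of different sex in the 2 libraries, Xist and Y-linked genes would part, and Xist was over 4-fold higher in replicate 1 while 3 of the 4 Y-linked genes were over 4-fold higher in replicate 2. A difference in sex is therefore a candidate explanation, with Uty, at 28.4 TPM in replicate 1, as the exception, and it stays a hypothesis since the labels used here give no sex. On X or Y lie 21 of the 576 genes over 4-fold apart that have a position, against 342 of all 9218 genes with a mean of at least 10 TPM, and effects of sex on genes of other chromosomes were not tested. Protein-coding X-linked genes with a mean of at least 10 TPM (292 genes) had a median difference of -0.25 log2 units against -0.16 for 7809 autosomal genes.

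The 636 genes over 4-fold apart between the libraries fell mostly in the low range. Genes that do not code for protein were over 4-fold apart more often, 20.1% of 1101 against 4.37% of 8117 protein-coding genes, from 8.52% of 223 lincRNA genes to 45.2% of 42 snRNA genes among the types counted separately, but they are not the whole cause, since 61.6% of such genes with a known type (355 genes) are protein-coding. Of genes at 100 to 1000 TPM 1.39% were over 4-fold apart and of genes at 10 to 100 TPM 7.42% (Fisher's exact test across genes, which are not independent, p = 3.89e-25). The fall did not continue at 1000 TPM or more, where 4 of 64 genes, 6.25%, were over 4-fold apart (Fisher's exact test, p = 0.0163 against 100 to 1000 TPM): Xist, Rpl35a, Gm25732 and mt-Nd2, named after their values were seen. Xist is 1 of these 4 genes and may be apart through a difference in sex, and the test was not repeated without it. With so few genes the test cannot decide whether the fall stops at 1000 TPM. Noise that falls with abundance therefore stays open, and there are no counts to separate it from differences between the animals.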
